A study of Mus musculus with 4 samples.

How the data were processed

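Gene expression was measured on 2-colour oligonucleotide arrays in livers of male mice of mixed B6/FVB background, 7 to 8 weeks old, kept on a selenium-sufficient diet. Per the labels, total RNA was extracted with Trizol, 15 µg was copied into cDNA from an oligo-dT primer, and the cDNA was coupled to Cy3 or Cy5. Wild-type liver was labelled with Cy3 and mutant liver with Cy5. Mutant and wild-type animals were littermates, with 1 biological replicate per array. The deposited table holds 1 column for each of 4 comparisons with wild type: DTrsp, A34, G37L and G37H. Each column is the authors' average over the biological replicates, 4 animals for DTrsp, A34 and G37L and 3 for G37H, per the labels. The spread between animals is therefore not in the values used here. No SD, interval or p-value across animals can be given, no animal can be left out in turn, and every comparison below is a description of 1 averaged value per gene.

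The values are log ratios made by the authors, per the labels' dye assignment, and are read here as log2 of mutant (Cy5) over wild type (Cy3). That direction is likely rather than stated. It rests on the dye labels alone, and the sample titles name wild type first. A turned ratio would change the sign of every value, list median and difference. With the ratio turned, the genes at least 2-fold higher would be 33.0% in DTrsp, 24.4% in A34, 61.2% in G37L and 52.7% in G37H of all genes at least 2-fold apart, and 60.1%, 35.0%, 45.7% and 34.7% after centring on column medians. The base of the logarithm is not given in the sources used here. Read as log10, the value farthest from 0 would be a 78331-fold ratio, beyond what an array scanner can record, so log10 was set aside. A natural logarithm is not excluded by the values, and its effect on the counts is given in the closing section. The normalization, background correction, spot filter, dye swaps and sharing of wild-type animals between comparisons are not given in the sources used here. The decimals of the values show that some averages rest on fewer arrays. Of 15478 values per column, 2174 in DTrsp (14.0%), 2093 in A34 (13.5%) and 893 in G37L (5.77%) were whole multiples of a 4-decimal step divided by 3, which an average over 4 arrays does not give. In G37H, 2234 (14.4%) were whole multiples of that step divided by 2, which an average over 3 arrays does not give.

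All 15478 probes had a value in each column. Of these, 12984 were named through the gene identifier of the platform annotation, matched to the mouse gene table of assembly GRCm38.p6, and 63 kept the annotation's own symbol. The 110 probes annotated with several genes and the 2321 not listed in the annotation were left unnamed. No genome coordinates are given, because no genome build goes with the probes. Probes of the same gene were averaged, giving 9285 genes, of which 6871 had 1 probe and 2414 had 2 or more. Signal intensities were not used here, so no gene can be called above or below background, and no list can be matched on expression level. The number of arrays limits the precision.

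No statistical test was run. A gene was counted where its log2 ratio was at least 1 (2-fold) above or below 0. The groups, the 35 gene lists, the rule for named genes and all alternatives not stated to be added later were chosen before the data were examined. Each list was described by the median log2 ratio of its measured members, by the members at least 2-fold apart, and by the place of its median among 10000 random lists of the same size drawn from all 9285 genes. Genes named in the text are the 12 highest and 12 lowest in each comparison with wild type, the 8 highest and 8 lowest in each difference between lines, any measured selenoprotein or selenocysteine factor, and up to 4 members of any other list with the largest absolute values in the comparison described. A gene outside this rule is said to have been chosen after its value was seen. Predicted transcripts count in the ranking and may be skipped. Lines were set against each other by subtracting their log2 ratios gene by gene.

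Column medians over genes were 0.16 in DTrsp, 0.07 in A34, -0.11 in G37L and -0.11 in G37H. The main values are as deposited, and list medians are also given relative to these column medians. Alternatives were thresholds of 1.5-fold and 3-fold, centring each column on its median, the median of probes, probes counted singly, and scaling each column to the median absolute deviation of DTrsp. Others were lists restricted to genes with 1 probe, means over members, Spearman correlation, and correlation without the 100 genes farthest from 0 in either comparison. Counting only genes with a value in all 4 comparisons moved nothing, since no value was missing. Alternatives chosen after seeing the data were centring on abundant transcripts, reading the counts as natural logs, the phase II list without the Gst, Mgst and Ugt families, the acute phase list without Mt1 and Mt2, and the lists that answer a comparison restricted to values whose decimals need an average over all arrays. The 134 abundant transcripts are the hepatocyte marker, ribosomal protein, oxidative phosphorylation and amino acid and urea cycle lists without phase II genes. Bootstrap ranges of a list median in the closing section come from 10000 draws of its genes with replacement.

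As a gauge of technical spread, probes of the same gene were compared. Over the 2389 genes with 2 to 5 probes, the SD between probes of a gene was 0.49 in DTrsp, 0.35 in A34, 0.37 in G37L and 0.38 in G37H. Over the 1791 genes with exactly 2 probes, the correlation between the probes was 0.13, 0.30, 0.44 and 0.32 in the same order. Probes of a gene can differ in transcript variant and in signal, so this spread is an upper view of the noise of a probe and says nothing of the animals.

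The calculation of list places was checked on simulated data made by permuting each column over genes. Permuting removes any likeness between members of a list and any trend with abundance. The shares of unchanged lists therefore follow from the design and do not bear on how real lists depart from random ones. In the permuted DTrsp column, 4.0% of 400 unchanged lists fell outside the central 95% of random lists, and the share was 5.75% for A34, 6.75% for G37L and 7.0% for G37H. Lists of 20 genes shifted by 0.5 lay above that range in 100% of 10 draws in every column. With a shift of 0.25 the share was 70.0% in DTrsp, 90.0% in A34, 80.0% in G37L and 80.0% in G37H. For correlations between comparisons, 20000 genes with no effect were simulated with equal spread per animal and all wild-type animals shared. For overlaps, 1000000 genes were simulated in the same way and the observed numbers of genes were taken from each end. No noise of the arrays themselves was added, and such noise would lower the simulated correlations and overlaps. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.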

Results

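The comparisons address mouse liver gene expression when the gene for the selenocysteine tRNA, Trsp, is removed or when mutant copies of it are carried as transgenes. Selenocysteine tRNA inserts selenocysteine into every selenoprotein, a class of proteins that includes antioxidant enzymes. DTrsp mice lacked Trsp in the liver. A34 mice carried 2 copies of a transgene with a T34-to-A34 change in the tRNA, G37L mice 2 copies of a transgene with an A37-to-G37 change, and G37H mice 16 copies of the latter. The labels used here do not say whether the transgenic livers also lacked their own Trsp. Each line was compared with wild-type littermates, labelled as the average over 4 animals for DTrsp, A34 and G37L and over 3 for G37H. The decimals show that part of the values rest on fewer arrays, at least 14.0% of probes in DTrsp, 13.5% in A34, 5.77% in G37L and 14.4% in G37H. There are no replicate values, so differences between lines or genes are not set against a spread between animals. Trsp itself had no named probe among the 9285 genes, so the targeted gene could not be checked.

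In DTrsp liver, genes of detoxification and glutathione metabolism were higher than in wild type. The list of phase II and NRF2 target genes holds conjugating and reducing enzymes of xenobiotic defence. It also holds oxidases such as Cyp2a5 and Fmo1, transporters, ferritins and regulators. Of its 57 measured members, 36 were at least 2-fold higher and 0 at least 2-fold lower. Their median log2 ratio was 1.22, which is 1.06 above the median of all genes, and 0 of 10000 random lists reached it. Centred on abundant transcripts the median was 0.71, and 22 genes stayed at least 2-fold higher. The highest members were the haem oxygenase Hmox1 at 4.03, the glutathione transferases Gstm3 at 3.46 and Gsta4 at 3.04, and the carboxylesterase Ces1g at 2.88. Glutathione transferases form families of similar sequence, so a probe may also read a relative of the gene it names.

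Selenoprotein transcripts had no common direction in DTrsp. The median of the 19 measured was -0.01, or -0.17 relative to all genes, and 1 was at least 2-fold lower and 1 at least 2-fold higher. Centred on abundant transcripts the median was -0.51, so the level of the class depends on the centring. Selenow was the lowest at -1.02, followed by the mitochondrial thioredoxin reductase Txnrd2 at -0.85, the deiodinase Dio1 at -0.67 and glutathione peroxidase Gpx1 at -0.55. Sephs2, a selenoprotein that makes the selenium donor, was the highest at 1.09, with Gpx2 at 0.78, the cytosolic thioredoxin reductase Txnrd1 at 0.71 and Gpx4 at 0.48. The 4 measured selenium-sensitive selenoproteins, Selenow, Gpx1, Gpx3 and Msrb1, had a median of -0.41, with 190 of 10000 random lists at or below it. The 6 selenium-resistant ones had a median of 0.34, and the 10 selenocysteine synthesis and insertion factors one of 0.10, both within the central 95% of random lists.

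Antioxidant and heat shock genes were also higher in DTrsp. The 22 glutathione, thioredoxin and antioxidant genes had a median of 0.85, with 8 at least 2-fold higher, and 6 of the 22 are also on the phase II list. The metallothionein Mt2 was the highest gene of all at 4.21, with Mt1 at 2.74 and the catalytic subunit of glutamate-cysteine ligase, Gclc, at 2.46. Of 18 heat shock genes, 6 were at least 2-fold higher, among them Dnajb1 at 1.43, Hspb1 at 1.31 and Hsph1 at 1.05, with a list median of 0.75. For both lists 0 of 10000 random lists were as high. Abundant transcripts as a group were above 0 as well. Median ratios were 0.56 for 23 hepatocyte markers, 0.53 for 52 ribosomal protein genes, 0.53 for 41 oxidative phosphorylation genes and 0.52 for 14 reference housekeeping genes. Fatty acid oxidation genes (28, median 0.52) and glucose metabolism genes (20, median 0.54) lay at the same level. Of the former, 1 was at least 2-fold higher, the fatty acid hydroxylase Cyp4a14 at 2.10, and 0 lower. Of the latter, 3 were at least 2-fold higher, Igfbp1 at 1.12 and the gluconeogenic enzymes Pcx at 1.08 and Fbp1 at 1.02, and 1 was lower, the glycolysis regulator Pfkfb3 at -1.06.

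Male-biased liver genes included 2 of the 3 lowest genes in DTrsp. Of 21 measured, 6 were at least 2-fold lower and 0 at least 2-fold higher: the steroid dehydrogenase Hsd3b5 at -3.01, the organic anion transporter Slco1a1 at -2.66, complement C6 at -1.49, Mup5 at -1.14, the oxysterol hydroxylase Cyp7b1 at -1.08 and Susd4 at -1.04, the last 2 of them chosen after their values were seen. The list median was -0.10, with 188 of 10000 random lists at or below it, but it was 0.24 over members with 1 probe. Of 13 female-biased genes, 4 were at least 2-fold higher, with Hamp2 at 1.71, Cyp2a4 at 1.70 and Cyp17a1 at 1.55, and the list median was 0.42, with 357 of 10000 random lists at or above it. Hsd3b4, close in sequence to Hsd3b5, was the lowest gene of all at -3.41. Other low genes were Adgrv1 at -2.48, the ferritin receptor Scara5 at -2.31, Serpina3b at -2.30, Fam25c at -2.05 and the histocompatibility gene H2-Bl at -1.92, with Slfn2, Ncam2 and Nnmt between -1.80 and -1.75. The twelfth lowest, at -1.73, is a predicted transcript. Other high genes were Stmn1 at 2.82, Mt4 at 2.80, Cyp2a5 at 2.65, the UDP-glucose dehydrogenase Ugdh at 2.62, Lgals1 at 2.49 and the xylosyltransferase Xylt1 at 2.46. Cyp2a4 and Cyp2a5 are nearly identical, and Mt1 and Mt2 are similar in sequence, so probes may not tell them apart.

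Over all 9285 genes, 304 were at least 2-fold higher and 150 at least 2-fold lower in DTrsp (67.0% higher). The column as a whole lay above 0, and after centring it on its median of 0.16 the counts were 172 and 259 (39.9% higher), so the balance of directions is not settled by these values. Probes of the same gene often differed, in this column and in the others. Of 117 probes at least 2-fold higher in genes with 2 probes, 28 (23.9%) had a partner that was too. Of 79 probes at least 2-fold lower, 8 (10.1%) did, with 39 partners below 0. In A34, G37L and G37H the shares were 13.9%, 40.7% and 30.8% for higher probes and 16.7%, 20.4% and 14.5% for lower ones. In DTrsp the balance also differed with the decimals of a value. Among probes whose decimals show an average over 4 arrays, 256 were at least 2-fold higher and 53 lower, against 37 and 89 among those averaged over 3. It was 150 and 46 among those with a step divided by 2, which an average over 2 or 4 arrays gives, and 151 and 161 among those with no fraction.

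**Figure D1:**
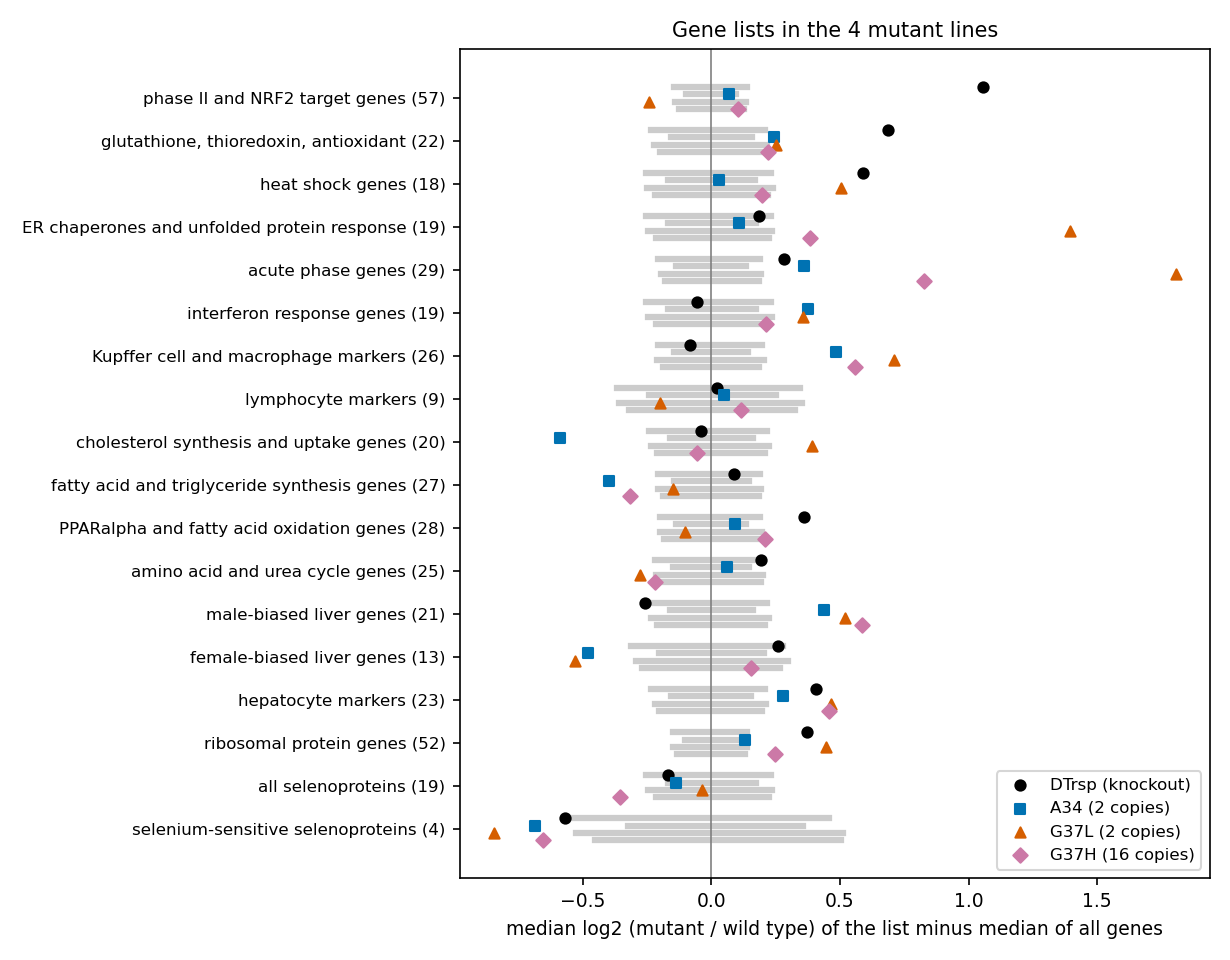
Median log2 ratio of mutant over wild type for 18 of the 35 gene lists, minus the median of all 9285 genes in the same column, with the number of measured members in brackets. Symbols are the 4 lines and each grey bar spans the central 95% of 10000 random lists of the same size; phase II genes lay at 1.06 in DTrsp and acute phase genes at 1.80 in G37L.

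In A34 liver, genes of cholesterol and fatty acid synthesis were lower than in wild type. The 20 measured cholesterol synthesis and uptake genes had a median of -0.52, or -0.59 relative to all genes, and 5 were at least 2-fold lower. These were Hmgcs1 at -1.56, Sqle at -1.39, Msmo1 at -1.30, Cyp51 at -1.19 and Idi1 at -1.18, all enzymes between acetyl-CoA and cholesterol; Idi1 was chosen after its value was seen. Of 27 fatty acid and triglyceride synthesis genes, 4 were at least 2-fold lower and 1 at least 2-fold higher, with Elovl6 at -1.51, the fatty acid transporter Cd36 at -1.23, Fasn at -1.15 and Gpam, the higher one, at 1.23. The list median was -0.33. For both lists 0 of 10000 random lists were as low.

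The phase II genes lay close to the median of all genes in A34. Their median was 0.14, or 0.07 relative to all genes, and 837 of 10000 random lists were as high. After centring on abundant transcripts it was -0.05. Of the 57, 5 were at least 2-fold higher, with Ugt1a6a at 1.39, Ces1g at 1.24, Osgin1 at 1.23 and Cyp2a5 at 1.22, and 0 were at least 2-fold lower. Among 19 selenoproteins, Selenow was at -1.47, Gpx1 at -0.83 and Gpx3 at -0.40, while Sephs2 was at 1.21, Selenoo at 0.88, Msrb1 at 0.77, Dio1 at 0.76 and Gpx4 at 0.57. Their median was -0.07, and their mean was 0.05. The 4 selenium-sensitive ones had a median of -0.62, as low as 0 of 10000 random lists, although Msrb1, 1 of the 4, was at 0.77.

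Macrophage, interferon response, acute phase and male-biased gene lists had medians above that of all genes in A34. The 26 Kupffer cell and macrophage markers had a median of 0.56, with the complement gene C1qc and the perforin-like Mpeg1 both at 1.12 and Cd74 at 1.11. Medians were 0.45 for 19 interferon response genes and 0.43 for 29 acute phase genes. The antigen transporter Tap1 was at 1.36 and the immunoproteasome subunit Psmb8 at 1.15. The 21 male-biased genes had a median of 0.51, with C9 at 1.16 and Cyp7b1 at 1.14, and the 13 female-biased genes one of -0.41. That median was 0.06 over female-biased genes with 1 probe. Each of these 5 medians, over all measured members, lay beyond all 10000 random lists. The 9 lymphocyte markers had a median of 0.12 and the 5 neutrophil markers one of 0.18. The median of 134 abundant transcripts was 0.19, and the plasma protein genes Mup2, Alb and Apoa1, chosen after their values were seen, were at 0.51, 0.42 and 0.34. The 27 lipoprotein genes had a median of 0.34, with 4 random lists as high. The highest single genes were Cap1 at 2.85, Xylt1 at 2.79, the immediate early gene Egr1 at 2.73, the immunoglobulin gene Ighm at 2.67 and Pth2 at 2.59. Ccdc40, Igkv3-2 and Igtp followed at 2.33, 2.10 and 2.04, and Rpp25, Clec2h, Csl and Klhdc9 lay between 1.68 and 1.82. Of these 12, 7 had values with no fraction of the 4-decimal step (Egr1, Ighm, Pth2, Igkv3-2, Igtp, Rpp25 and Klhdc9), against 30.7% of probes in the column. Such a value can come from a single array or, by chance, from an average. The immunoglobulin gene Igkc, chosen after its value was seen, was at -0.15. The lowest was Cyp4a14 at -3.10, then the lysolipid transporter Mfsd2a at -1.85, Pttg1 at -1.76, the xanthine dehydrogenase Xdh at -1.56 and Fcgr1 at -1.55. Lims1, Serpina7 and Igfbp1 lay at -1.46, -1.44 and -1.38. In all, 130 genes were at least 2-fold higher and 42 at least 2-fold lower (75.6% higher), and 106 and 57 (65.0% higher) after centring. Scaled to the median absolute deviation of DTrsp, they numbered 448 and 154. Centred on abundant transcripts they numbered 73 and 99, so the balance of directions is not settled.

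**Figure D2:**
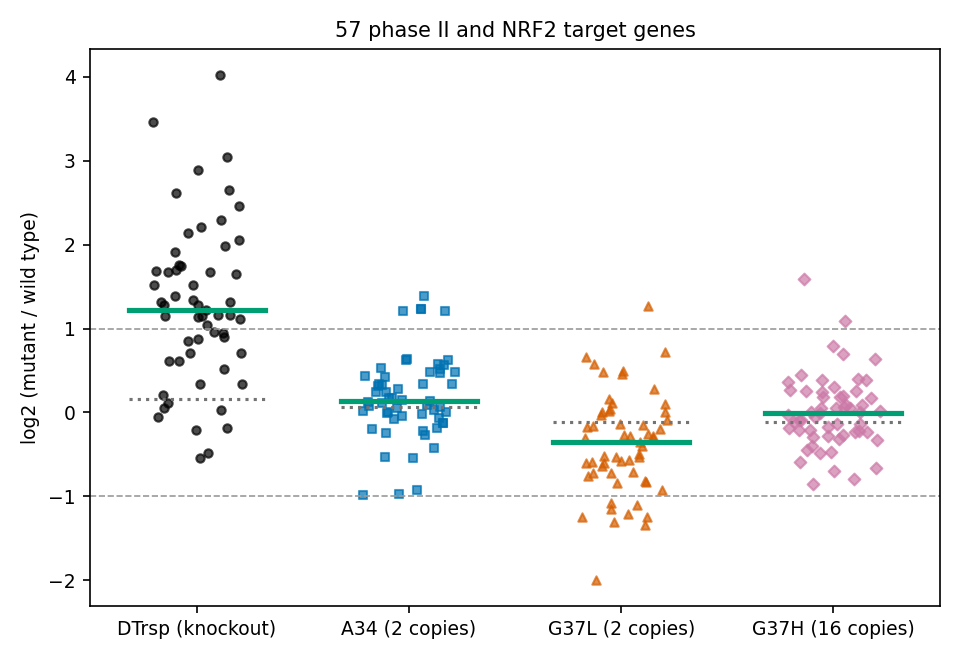
Log2 ratio of mutant over wild type for each of 57 phase II and NRF2 target genes in the 4 lines; each symbol is a gene, green lines are list medians, dotted lines the median of all genes and dashed lines 2-fold. The median was 1.22 in DTrsp, 0.14 in A34, -0.35 in G37L and -0.01 in G37H.

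In G37L liver, acute phase genes and chaperones of the endoplasmic reticulum were higher than in wild type. Of 29 acute phase genes, mostly for plasma proteins that hepatocytes release in inflammation but also for intracellular proteins such as the metallothioneins Mt1 and Mt2, 23 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.69, or 1.80 relative to all genes. The serum amyloid genes Saa2 and Saa1 were at 4.79 and 4.31, Saa3 at 3.61, the lipocalin Lcn2 at 4.47 and the pentraxin Apcs at 3.35. Saa1 and Saa2 are too alike for a probe to separate with certainty. Of 19 genes for chaperones of the endoplasmic reticulum and the unfolded protein response, 11 were at least 2-fold higher, with Creld2 at 3.11, Manf at 2.35, Sdf2l1 at 1.90 and the main chaperone Hspa5 at 1.78. Their median was 1.28. For both lists 0 of 10000 random lists were as high. Beside these, 26 Kupffer cell and macrophage markers had a median of 0.60, with 7 at least 2-fold higher, 5 neutrophil markers, Lcn2 included, one of 0.46 and 9 lymphocyte markers one of -0.31.

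Phase II genes were lower in G37L. The median of the 57 was -0.35, or -0.24 relative to all genes, 9 were at least 2-fold lower and 1 at least 2-fold higher, and 5 of 10000 random lists were as low. The oxidases Cyp2a5 and Fmo1 were at -2.0 and -1.34, Gsta1 at -1.31 and Hmox1, the higher one, at 1.27. Cholesterol synthesis genes had a median of 0.28, with Sqle at 1.5, Idi1 at 1.14 and Cyp51 at 1.01. The 25 amino acid and urea cycle genes had a median of -0.39, with the transsulfuration enzyme Cth at -2.47, Oat at -1.34 and Prodh at -1.27. The 17 circadian clock genes had a median of -0.41, with Alas1 at -1.52 and Wee1 at -1.06. Male-biased genes had a median of 0.41, female-biased genes one of -0.64 and the 134 abundant transcripts one of 0.20. The plasma protein genes Mup2, Alb and Apoa1, chosen after their values were seen, were at 0.68, 0.67 and 0.73. These lay above the male-biased median, and Mup2 is on that list. The median of the 19 selenoproteins was -0.15, or -0.04 relative to all genes. Selenow was at -1.60, Txnrd2 at -1.42, Gpx3 at -0.96 and Gpx1 at -0.95, against Selenok at 0.61 and Selenop at 0.34. The 4 selenium-sensitive ones had a median of -0.96, with 18 of 10000 random lists at or below it. Among the insertion factors, Sephs1 was at 1.14 and nucleolin, Ncl, at -1.15.

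Other high genes in G37L were Mt2 at 4.46, Mt1 at 3.94, the glutathione transferase Gstp3 at 3.63, Cap1 at 3.18, the receptor kinase Alk at 3.13 and Mt4 at 3.12. The lowest genes were Rgs16 at -2.80, Dct at -2.47, Inpp5k at -2.29, Sucnr1 at -2.23, Dchs1 at -2.21 and Loxl2 at -2.16. Mfsd2a, Asic5, Igfbp5 and Cir1 lay between -2.14 and -2.07, and an olfactory receptor gene, Olfr1495, at -2.21. Of the 12 lowest, 8 had values with no fraction of the 4-decimal step (Inpp5k, Sucnr1, Olfr1495, Dchs1, Loxl2, Asic5, Igfbp5 and Cir1), against 37.8% of probes in the column. In all, 233 genes were at least 2-fold higher and 368 at least 2-fold lower (38.8% higher). After centring the column on its median of -0.11 the counts were 301 and 253 (54.3% higher). Centred on abundant transcripts they were 149 and 728, so the balance of directions is not settled.

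In G37H liver, with 16 transgene copies, the acute phase genes were again higher, though by less. Their median was 0.71, or 0.82 relative to all genes, and 9 of 29 were at least 2-fold higher and 1 at least 2-fold lower. Mt2 was at 4.43, Mt1 at 3.16, Saa1 at 2.27 and the serine protease inhibitor Serpina3n at 1.65. In DTrsp, Mt2 and Mt1 were also high, at 4.21 and 2.74, while Saa1 and Serpina3n were at 0.05 and -0.22. Male-biased genes had a median of 0.47, with the odorant-binding Obp2a at 1.74 and Cyp7b1 at 1.26, and 26 Kupffer cell and macrophage markers one of 0.44, with Vsig4 at 1.56 and H2-Aa at 1.49. For these 3 lists 0 of 10000 random lists were as high. The median of 134 abundant transcripts was 0.12, but some plasma protein genes lay about as high as the acute phase median. Alb, Apoa1 and Mup2, chosen after their values were seen, were at 0.72, 0.70 and 0.79, and Mup2 is on the male-biased list. The 40 phase I cytochrome P450 genes had a median of 0.28, with Cyp2b10 at 2.84, Cyp2c70 at 1.59 and Cyp4a14 at -1.32. Fatty acid and triglyceride synthesis genes had a median of -0.43, with Cd36 at -1.92, Srebf1 at -1.68, Pparg at -1.59 and Acly at -1.53, and 8 of 10000 random lists were as low.

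Selenoproteins had their lowest class median in G37H, at -0.47, or -0.35 relative to all genes. It would be their highest with the ratio turned. Of 19, 17 were below 0, 2 at least 2-fold lower and 0 at least 2-fold higher, and 7 of 10000 random lists were as low. Over the 8 whose decimals show an average over all arrays, the median was -0.28, with 0 at least 2-fold lower. Selenow was at -1.59, Txnrd2 at -1.53, Gpx3 at -0.85, Selenov at -0.71 and Msrb1 at -0.69, with Selenop at 0.32 and Gpx4 at 0.14 above 0. The 4 selenium-sensitive ones had a median of -0.77, with 52 of 10000 random lists at or below it. Phase II genes had a median of -0.01, which became 0.11 relative to all genes, and a mean of 0.01, with 2 at least 2-fold higher. The highest single genes were Gstp3 at 4.89, Mt4 at 3.32, the protease inhibitor A2m at 3.24 and Cap1 at 3.11. Abhd1 and Bcl7c were at 2.37 and 2.26, the cell cycle inhibitor Cdkn1a at 2.17 and Myc at 2.14. The lowest were the apolipoprotein Apoa4 at -2.64, the peroxisomal transporter Slc25a17 at -2.52, Cth at -2.35, B4galnt1 at -2.18 and Rgs16 at -2.12. Micos10, Ifi205, Asic5, Ddx6, Eepd1 and Oat followed between -2.09 and -1.89. In all, 258 genes were at least 2-fold higher and 288 at least 2-fold lower (47.3% higher), and 342 and 182 (65.3% higher) after centring. Centred on abundant transcripts, 441 were at least 2-fold lower. Of probes whose decimals show an average over 3 arrays, 2.41% were at least 2-fold apart, against 11.9% of those averaged over fewer and 8.67% of those with no fraction.

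**Figure D3:**
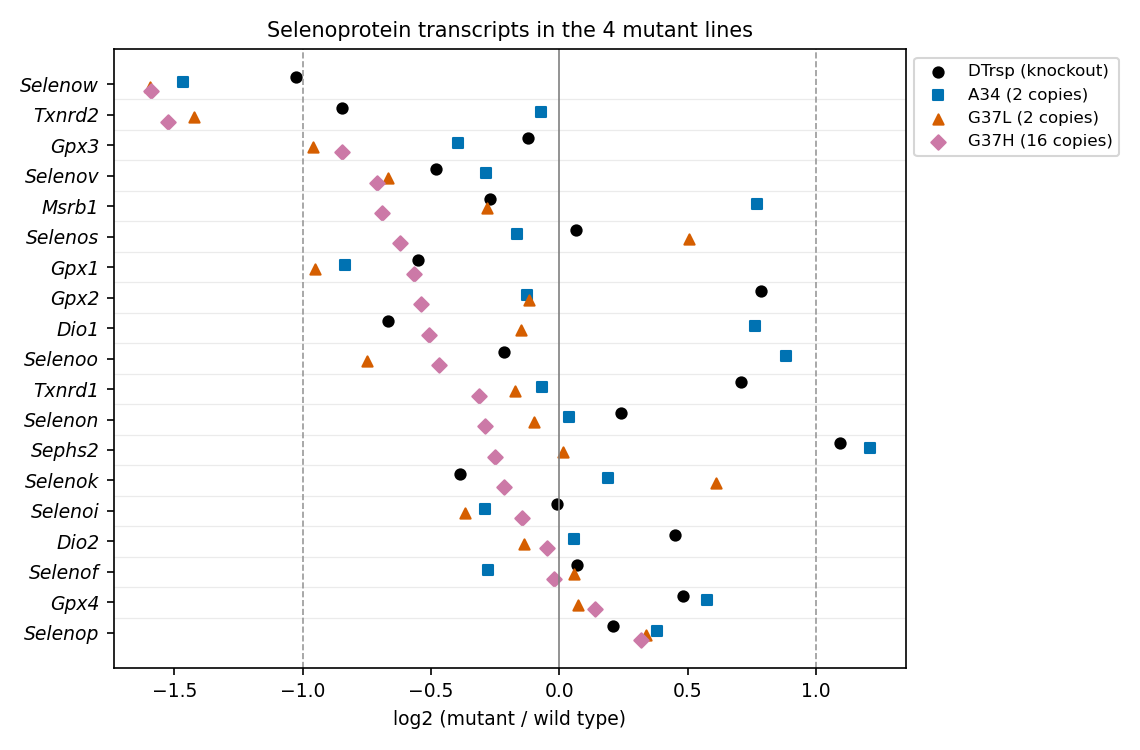
Log2 ratio of mutant over wild type for each of the 19 measured selenoprotein transcripts in the 4 lines, ordered by G37H; each symbol is a line's average and dashed lines mark 2-fold. Selenow lay between -1.60 and -1.02 in the 4 lines.

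The transgenic lines were set against the knockout gene by gene. Phase II genes differed from DTrsp in each line. Each difference subtracts the same DTrsp column, where this list was already high, so these results largely restate that one. The median difference was -1.04 in A34, with 30 of 57 at least 2-fold lower, -1.55 in G37L, with 38, and -1.33 in G37H, with 38, and 0 of 10000 random lists were as low in any of them. Relative to all genes these were -0.93, -1.27 and -1.05. Gstm3 differed by -3.14, -3.45 and -3.21 in the same order. Male-biased genes were the other way, with median differences of 0.57, 0.47 and 0.32, or 0.67, 0.75 and 0.61 relative to all genes. Hsd3b4 differed by 4.02 in A34 and 3.18 in G37H, and Slco1a1 by 3.02 and 3.15. Selenoproteins had median differences of -0.20 in A34, -0.40 in G37L and -0.42 in G37H (-0.096, -0.12 and -0.13 relative to all genes), none outside the central 95% of random lists, and the mean difference in A34 was 0.07. The lipid genes Cyp4a14 and Cd36 were high in the knockout and low in every transgenic line, with differences from -5.2 to -3.42 for Cyp4a14 and from -4.32 to -3.63 for Cd36. A2m differed by 3.39 in G37L and 4.61 in G37H, Scara5 by 4.12 and 3.89, and Gstp3 by 4.32 in G37H. Genes at least 2-fold higher and lower than in the knockout numbered 416 and 380 in A34 (52.3% higher), 368 and 940 in G37L (28.1%) and 396 and 829 in G37H (32.3%). With both columns centred they numbered 542 and 283 (65.7%), 639 and 449 (58.7%) and 678 and 368 (64.8%), so the excess of lower genes in G37L and G37H does not hold. With the ratio turned, the shares higher would be 47.7%, 71.9% and 67.7%, and 34.3%, 41.3% and 35.2% centred. Of 304 genes at least 2-fold higher in DTrsp, 11 were so in A34, 21 in G37L and 15 in G37H, against 4.26, 7.63 and 8.45 for independent lists. In the opposite direction, 8, 18 and 15 of the 304 were at least 2-fold lower in these lines. Of 150 lower in DTrsp, 4, 18 and 11 were lower in the same lines, against 0.679, 5.95 and 4.65, while 6, 9 and 15 were at least 2-fold higher. Shared genes therefore do not show a common direction with the knockout in every line. With all wild-type animals shared and no effect, simulated overlaps were 33.1, 51.4 and 47.5 for higher genes and 9.39, 42.6 and 29.8 for lower genes, above each observed count. Array noise, left out of the simulation, would lower the simulated overlaps.

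Transgene copy number was compared between G37H and G37L. These are separate lines of 3 and 4 animals, so a difference between them goes with the line as much as with the number of copies. The acute phase genes had a median difference of -1.01, with 15 of 29 at least 2-fold lower in G37H, and the 19 chaperone and unfolded protein response genes one of -1.05, with 10 lower. For both, 0 of 10000 random lists were as low. The largest differences were Lcn2 at -3.81, Saa2 at -3.4, the thyroxine carrier Serpina7 at -3.26, Tifa at -3.04, the neutrophil chemokine Cxcl1 at -2.99, Slc41a2 at -2.91, Atf5 at -2.51 and Fgl1 at -2.51. In the other direction, cytochrome P450 genes had a median difference of 0.56, with 9 of 40 at least 2-fold higher in G37H, and phase II genes one of 0.32. Single genes higher in G37H were Loxl2 at 3.28, Cdkn1a at 2.83, Ces1g at 2.75, Zfp959 at 2.73, Rnf186 at 2.68 and Ces1d at 2.53. The selenoprotein median differed by -0.08. At least 2-fold apart were 378 genes higher and 248 lower in G37H. The shared counts were the largest of the 6 pairs of lines. Of 233 genes at least 2-fold higher in G37L, 80 were so in G37H, against 6.47 for independent lists, and of 368 lower, 54 were lower, against 11.4. With all wild-type animals shared and no effect, simulated overlaps were 37.2 and 57.3, above the observed overlap for lower genes and below it for higher genes, part of which may come from shared wild-type RNA. These simulated overlaps leave out array noise, which would lower them.

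**Figure D4:**
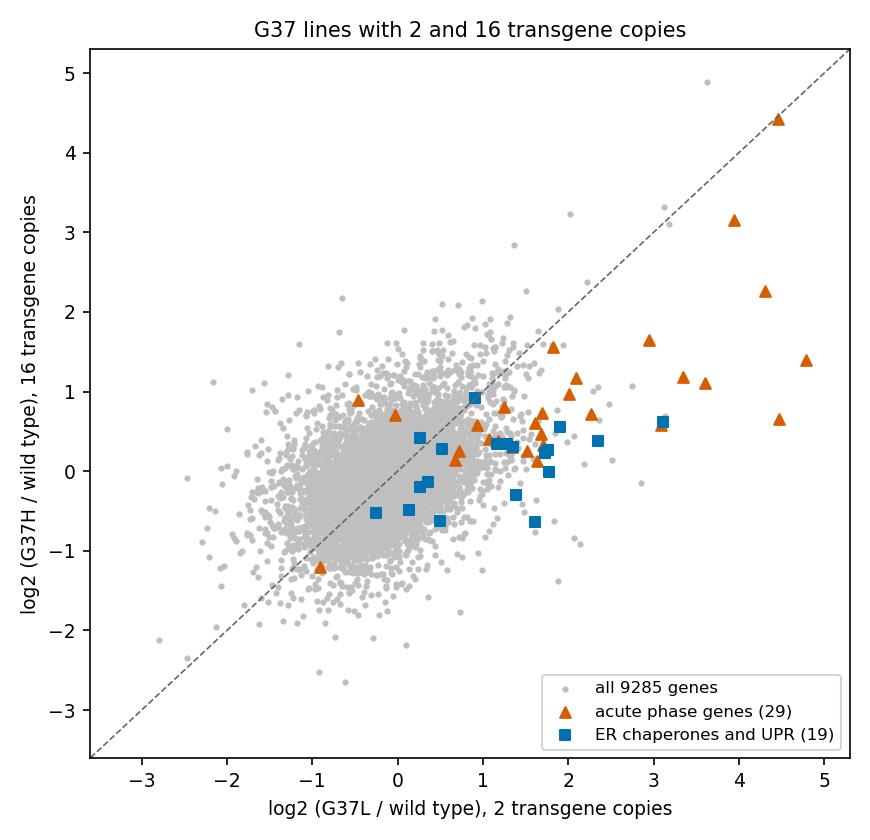
Log2 ratio of G37H over wild type against that of G37L over wild type for 9285 genes (grey), with 29 acute phase genes as triangles and 19 genes of endoplasmic reticulum chaperones and the unfolded protein response as squares. The dashed line marks equal values; the median difference, G37H minus G37L, was -1.01 for the acute phase genes and -1.05 for the chaperone genes.

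The kind of mutation was compared between A34 and G37L, each with 2 copies. Acute phase genes had a median difference, A34 minus G37L, of -1.49, with 18 of 29 at least 2-fold lower in A34, chaperone genes one of -0.67 and cholesterol synthesis genes one of -0.37, or -1.69, -0.87 and -0.56 relative to all genes. Phase II genes had a median difference of 0.57, or 0.38 relative to all genes. Lcn2 differed by -4.30, Saa2 by -4.15, Fndc9 by -3.57 and Creld2 by -3.39, while Ighm differed by 3.71, Xylt1 by 3.26, Cyp2a5 by 3.22 and Rgs16 by 3.10. The selenium-sensitive selenoproteins differed by a median of 0.35, or 0.15 relative to all genes, within the central 95% of random lists. At least 2-fold apart were 656 genes higher and 237 lower in A34 (73.5% higher), and 387 and 374 (50.9% higher) with both columns centred. With the ratio turned, the shares higher would be 26.5% and 49.1%.

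Across the 9285 genes, which are not independent replicates, the 6 pairs of comparisons had Pearson correlations of 0.04 for DTrsp and A34, 0.13 for DTrsp and G37L, 0.11 for DTrsp and G37H, 0.19 for A34 and G37L, 0.24 for A34 and G37H, and 0.47 for G37L and G37H. Had all wild-type animals been shared and no line had an effect, simulation gave 0.50, 0.50, 0.44, 0.49, 0.43 and 0.43 in the same order. The simulation left out the noise of the arrays, which would lower these values. For 5 of the 6 pairs the observed value lay below the simulated one, and for G37L and G37H it was 0.47 against 0.43. Whether animals were shared is not stated. Mutant and wild-type animals were littermates, per the labels, so full sharing would need litters common to the lines. The covariance was not simulated, since that needs the spread between animals, so part or all of a correlation may come from shared wild-type RNA. Genes at least 2-fold higher in A34, G37L and G37H alike numbered 15 and genes lower in all of them 6, among these Selenow, Cth, Cyp4a14 and Cd36. For these counts no value was simulated with shared wild-type animals and no effect.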

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

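Of the tests reported in this part, the comparison with abundant transcripts, the phase II genes outside 3 families, the immune cell markers, the value needed by a single animal, the Y-linked gene and the female-biased list were chosen after the results they bear on had been seen.

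Of 430 genes that the rule for named genes takes in any comparison, 40 were at least 2-fold higher than wild type in a line and at least 2-fold lower in another. None of these differences was tested, since each line has 1 averaged value, and a search for single animals far from the rest could not be made. The distance between the highest and the lowest line was 5.2 for Cyp4a14 and 2.98 for Ppl, 2.84 for Pttg1 and 2.51 for Igfbp1 (DTrsp minus A34). For DTrsp minus G37L it was 4.65 for Cyp2a5, 4.04 for Ces1g, 3.45 for Ugt2b35, 3.37 for Gsta1, 3.35 for Gstt3, 2.81 for Cyp8b1 and 2.5 for Fmo1. For DTrsp minus G37H it was 4.32 for Cd36, 3.74 for Slc25a17, 3.54 for Tceal8, 3.22 for Atf5, 2.91 for Hamp2 and 2.47 for Rtn4. Lowest in DTrsp were A2m (4.61), Fam25c (3.61), Cypt2 (3.04), Elac1 (2.58), Cyp7b1 (2.34) and Pfkfb3 (2.12), all highest in G37H, Scara5 (4.12), Adgrv1 (3.96), Nnmt (2.91) and Mcm3 (2.37), highest in G37L, and H2-Bl (3.26), highest in A34. Between transgenic lines it was 3.57 for Fndc9, 3.32 for Serpina7, 2.89 for Sqle, 2.32 for Idi1 and 2.2 for Cyp51 (G37L minus A34), 3.71 for Ighm, 2.81 for Tmco4 and 2.45 for Gpam (A34 minus G37L), 3.28 for Loxl2, 2.73 for Zfp959 and 2.68 for Rnf186 (G37H minus G37L) and 2.78 for Fcgr1 (G37H minus A34).

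Phase II genes were higher than wild type in DTrsp, in a column where abundant transcripts also lay above 0. A ratio that rises with transcript abundance would place them no higher than other abundant liver transcripts. The phase II median exceeded that of 134 abundant transcripts by 0.71, the highest of 10000 draws of 57 abundant transcripts had a median of 0.67, and 35 of the 57 phase II genes lay above the highest abundant transcript, at 1.09. Cross-hybridisation within the Gst, Mgst and Ugt families would need the pattern to rest on those families, but the 35 members outside them had a median of 1.28, with 23 at least 2-fold higher. An abundance trend may still account for part of the size, since 22 rather than 36 genes stay at least 2-fold higher after centring on abundant transcripts, and the loss of Trsp remains an untested biological explanation.

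Acute phase and chaperone genes were higher in G37L, with 2 copies, than in G37H, with 16. If RNA from added immune cells were the source, their own markers would be raised at least as much. Markers do not bear on hepatocytes responding to immune cells, so that reading stays open for the acute phase genes. The 9 lymphocyte and 4 neutrophil markers outside the acute phase list had medians of -0.31 and -0.11 and none above 1.23. The highest class median, of 26 macrophage markers at 0.60 (95% bootstrap range over genes 0.34 to 0.80), lay 1.09 below that of the acute phase genes (1.34 to 2.27). It lay 0.68 below that of the chaperone genes, whose range of 0.50 to 1.73 overlaps it, and Mpeg1 at 1.60 and Ctss at 1.37 exceed their median, so for the chaperone genes immune cells and an effect of the line cannot be told apart. Inflammation in 1 of the 4 animals alone would need a log2 ratio of 6.77 in that animal for the acute phase median, and 5.12 for the chaperone genes, with the other 3 at 0, both within the range of a 16-bit scanner. Lcn2 and Mt2, whose decimals show averages over 4 arrays, would need 17.9 and 17.8, beyond that range. Mt2 was also at 4.21 in DTrsp, where Saa1, Saa2 and Saa3 were at 0.05, 0.22 and -0.16. Mt2 can thus be high without the serum amyloid genes and does not bear on inflammation. These top genes alone do not settle the list. For the list, the line's effect and inflammation in a single animal cannot be told apart, nor is the line separable from the copy number.

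Some male-biased genes were lower in DTrsp, although the list median of -0.10 became 0.24 over members with 1 probe. Female animals in the DTrsp group would leave the Y-linked Eif2s3y, chosen after its value was seen, far below 0. Its single probe was at -0.086 in DTrsp, against -0.70 in A34, -1.05 in G37L and -0.54 in G37H, where male-biased genes were higher. A probe at background would read near 0 in either sex, and intensities were not used here, so this value does not settle the question. The labels give the animals as male. A shift towards the female pattern of liver genes would need the female-biased list above nearly all random lists. Its median was 0.42, with 357 of 10000 random lists at or above it, which leaves the explanation open, as is the effect of Trsp loss itself.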

How the results depend on the processing

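The alternatives that read values as natural logs, centre on abundant transcripts, drop gene families or keep only values averaged over all arrays were chosen after seeing the data. No paired analysis was possible because each comparison has 1 averaged value and no replicate. Leaving out an animal was not possible for the same reason, and without intensities the effect of dim spots was not analysed here. The median of probes moved none of the 8 counts by more than 1.5 times, and Spearman correlation and removal of far genes moved none of the 6 correlations by 0.1 or more. Reading values as natural logs multiplies every named gene's log2 value and turns none. Where no reason is given, the cause of a shift was not tested.

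At 1.5-fold, genes higher and lower than wild type numbered 1448 and 646 in DTrsp, 706 and 246 in A34, 692 and 1424 in G37L, and 678 and 1214 in G37H. At 3-fold they numbered 61 and 15, 22 and 3, 61 and 59, and 51 and 36. Probes counted singly gave 594 and 349, 372 and 66, 458 and 669, and 461 and 545. This setting counts more probes than genes, 2431 of them unnamed, and leaves out averaging over probes, and their shares in the shift were not tested. Values read as natural logs gave 950 and 440, 442 and 151, 512 and 1030, and 536 and 827, since every ratio grows. Centring on abundant transcripts gave 77 and 861 in DTrsp, 73 and 99 in A34, 149 and 728 in G37L, and 441 lower in G37H. Centring each column on its median gave 172 and 259 in DTrsp and 182 lower in G37H. Scaling to the same median absolute deviation gave 448 and 154 in A34.

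For differences from the knockout at 1.5-fold, genes higher and lower numbered 1189 and 1423 in A34, 861 and 2612 in G37L, and 868 and 2584 in G37H. With columns centred on their medians they numbered 639 and 449 in G37L and 678 and 368 in G37H, and for A34 minus G37L 387 and 374. Scaling gave 691 higher for A34 minus DTrsp.

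The median of all selenoproteins after centring on column medians was -0.17 in DTrsp and -0.35 in G37H. Centred on abundant transcripts it was -0.51 in DTrsp, -0.26 in A34, -0.35 in G37L and -0.59 in G37H. Their mean was 0.046 in A34 and -0.32 in G37L. The phase II median after centring on column medians was 1.06 in DTrsp, 0.068 in A34, -0.24 in G37L and 0.11 in G37H. Centred on abundant transcripts it was 0.71, -0.054, -0.55 and -0.13 in the same order. Over members with 1 probe it was 1.32 in DTrsp, 0.077 in A34 and -0.51 in G37L, and scaled it was 0.20 in A34. Without the Gst, Mgst and Ugt families it was 0.084 in A34, -0.27 in G37L and -0.12 in G37H. In DTrsp, 20 phase II genes were at least 3-fold higher, and 22 at least 2-fold higher after centring on abundant transcripts.

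For A34 minus DTrsp the phase II median was -0.91 scaled and -0.95 centred on column medians, and centred it was -1.28 for G37L minus DTrsp and -1.06 for G37H minus DTrsp. The cholesterol synthesis median in A34 was -0.75 scaled, -0.71 centred on abundant transcripts and -0.65 over members with 1 probe, and for A34 minus G37L it was -0.55 both scaled and centred on column medians. The acute phase median in G37L was 1.80 centred on the column median, 1.49 centred on abundant transcripts and 2.05 over members with 1 probe, and the mean was 2.03. The chaperone median in G37L was 1.08 centred on abundant transcripts. Over values averaged over all arrays, medians were -0.28 for 8 selenoproteins in G37H, 0.26 and -0.53 for 28 and 30 phase II genes in A34 and G37L, -0.71 for 8 cholesterol synthesis genes in A34 and 0.89 for 12 chaperone genes in G37L.

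Under the alternatives, 81 values of list medians lay on the other side of 0 from the main one, 12 of them for main medians outside the central 95% of random lists, which follow. Centred on abundant transcripts, the medians were -0.073 for phase I cytochrome P450 genes in DTrsp, -0.12 for lipoprotein genes in DTrsp and -0.030 in G37L, and -0.030 for fatty acid oxidation genes in G37H. They were -0.060 for antioxidant genes in G37L and -0.017 in G37H, -0.062 for acute phase genes in DTrsp, and -0.030 for p53 and integrated stress response genes in G37L. They were -0.054 for endothelial markers in DTrsp and -0.020 for reference housekeeping genes in G37L. Each main median of these 10 lay above 0 and below that of the abundant transcripts, so subtracting the latter turns the sign. Over genes with 1 probe, male-biased genes had a median of 0.24 in DTrsp and female-biased genes one of 0.057 in A34, and the cause was not tested.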

Other observations

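Of 14 p53 and integrated stress response genes, 3 were at least 2-fold higher in G37H and 1 at least 2-fold lower: Cdkn1a at 2.17, Myc at 2.14, Gadd45g at 1.87 and Atf5 at -1.77. The list median in G37H was 0.07, with 717 of 10000 random lists at or above it. Of 19 cell cycle genes, 3 were at least 2-fold higher in G37L, with cyclins Ccnd1 at 1.53 and Ccna2 at 1.43 and the replication factor Mcm3 at 1.07, and 0 at least 2-fold lower; the list median was -0.18. Of 21 bile acid genes in DTrsp, 4 were at least 2-fold higher and 2 at least 2-fold lower, with the sterol hydroxylase Cyp8b1 at 1.52 and the exporters Abcc3 at 1.39 and Abcc2 at 1.22, and the median was 0.25.

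The 16 endothelial markers had a median of 0.45 in DTrsp, which became -0.054 after centring on abundant transcripts. The 22 stellate cell and fibrosis markers had a median of 0.04 in DTrsp, with the basement membrane collagen Col4a2 at 1.32, and the 7 biliary and progenitor markers one of 0.26. Of 8 erythroid and haemoglobin markers, 3 were at least 2-fold higher in DTrsp. These were the beta globin genes Hbb-b1 at 1.37 and Hbb-b2 at 1.34, which are close in sequence, and the alpha globin gene Hba-a1 at 1.13. The 9 exocrine pancreas, adipose, muscle and kidney markers had a median of -0.32 in DTrsp, with creatine kinase Ckm at -1.31 and elastase Cela1 at -1.26. The 2431 unnamed probes held 124 at least 2-fold higher and 55 at least 2-fold lower in DTrsp.

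Genes at least 2-fold higher in all 4 lines were Mt1, Mt2 and Mt4, and Selenow was at least 2-fold lower in all of them. Each was read by 1 probe, and the Mt4 probe may also read Mt1 or Mt2. Mutant liver was labelled with Cy5 in every line. A dye bias of single genes or shared wild-type RNA could therefore also give the same direction in all 4, and neither was tested. Cap1 was at 2.85 in A34, 3.18 in G37L and 3.11 in G37H, against 0.33 in DTrsp.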
